A study of Gallus gallus with 8 samples.

How the data were processed

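Chick (Gallus gallus) embryos were harvested, dissected and pooled, RNA was extracted with Trizol, and polyadenylated RNA was made into libraries and sequenced from both ends with reads of 36 bases on an Illumina HiSeq sequencer, per the labels' protocols. Each of the 8 groups (sinoatrial node, left atrium, ventricle apex, atrioventricular junction, pacemaker progenitor field, and anterior, left and posterior lateral plate mesoderm) is 1 library of pooled tissue, so no group has a replicate. Bowtie and TopHat were used, per the submitters' processing notes, without versions. The genome build, gene annotation, counting program and use of strand were not given in the sources used here.

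The 8 deposited tables each list 17778 genes with chromosome, strand, start and end. Per the file headers, each holds a normalized column of its own library. Of the 8, 7 also hold a column of read counts, and the junction's table holds the normalized column of the posterior mesoderm instead. The normalized column is in CPM, counts divided by the library's total, and sums to its full scale in each library, so the authors' normalization is plain scaling to the total count. Per the file headers, each count column belongs to a library other than that of its table, so the deposited counts were matched to libraries by the name in the header and not by the table they stood in. This gave deposited counts for 7 libraries, and dividing them by their sum gave back the CPM of the library of the same name to within 4.9e-11 CPM. The counts of the posterior mesoderm were recovered from its deposited CPM, where 100% of values were whole multiples of 1 read within 0.01. The posterior mesoderm's CPM column thus stood in 2 tables and was used once. Every column was used.

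The gene names in the tables mix symbols, database entry names and identifiers. Names were matched to a chicken RefSeq gene table (assembly GRCg7b), which served only for names and for the order of neighbouring genes. Current symbols matched 7542 genes, older symbols 728, gene identifiers 455 and checked entry names 139, while 8914 had no match. An entry name such as CXA5 for GJA5 or MLRA for MYL2 was accepted only where at least 2 neighbouring genes in the table and in the reference were shared, and 61 other matches were dropped where no neighbour was shared. In all 8612 genes carried a symbol, the remaining matches leading to a locus identifier, and 2926 Ensembl identifiers and 2718 protein accessions had no name and stayed in the counts without being named. SHOX2, TBX18, IRX4, MYH15, AMHC1, WNT5A and NODAL were to be reported but found no match by name and are not analysed here. Values of some other genes are not reported here. Coordinates are those of the deposited tables.

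Counts were scaled between libraries with TMM factors (edgeR 4.0.16 in R 4.3.3) over all 8 libraries, which ran from 0.848 in the atrium to 1.18 in the left mesoderm. All levels in the text are CPM after that scaling. The ratio of a gene was log2 of CPM + 1 in 1 library over CPM + 1 in the other, which understates the difference of genes at low level. A gene was called when this ratio was at least 1 or at most -1 against every reference library, the higher library held at least 5 CPM, and the exact (Clopper-Pearson) 95% interval of the ratio of counts excluded 1. These intervals cover counting error only. The threshold compares libraries, not conditions, and no p-value was computed. A fold is the ratio of CPM to the nearest reference. Where the lower library had 0 counts the fold was taken against a floor of 3 counts in the shallowest such reference and is a lower bound, and 1 to 3 counts are given with their interval. In total 7 comparisons were made, with genes at 5 CPM or more in at least 1 of their libraries counted as expressed. 1 read was worth 0.0582 CPM in the deepest library and 0.0975 in the shallowest, and 3 reads 0.174 to 0.292.

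Before the data were examined, 25 lists with 502 gene entries (heart cell types, signalling pathways, patterning genes and markers of other cell types) were fixed, of which 280 were found by name. For a list with at least 3 expressed members, the median over members of the log2 ratio to the mean of the references was compared with 10000 random lists of the same size drawn from genes in the same 20 bins of mean expression. The percentile describes these libraries and is not a test. This gave 163 list results. Some genes, such as TBX3 and BMP4, stand in more than 1 list, so these results are not independent. The genes named in the text were also chosen by a rule fixed in advance: the 12 higher and 8 lower called genes with the largest ratio among those at 10 CPM or more with a symbol, up to 4 called members of each list described or otherwise its 2 highest expressed, and a short set of heart and mesoderm genes in every comparison. Exceptions are stated where they occur. Similarity between libraries was the Spearman correlation across 12984 genes with at least 1 CPM in some library, for all 28 pairs.

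The calling rule was tested on simulated counts over 17778 genes. Increases of 3-fold or 6-fold were put into some genes with a mean of at least 5 CPM, in the library compared with its references. Recovery of decreases, and of changes in genes below 5 CPM, was not simulated. The counts were drawn from each gene's mean level over the 8 libraries, heart and mesoderm together, and from the totals of the real libraries. With counting noise alone, 99% to 100% of 3-fold changes were recovered and no unchanged gene was called in the 6 comparisons simulated. With 20% variation added between libraries, a value assumed and not measured, 78% of 3-fold changes were recovered in the node comparison, 97% in atrium against ventricle, 78% in the junction, 73% in the pacemaker field, 94% in anterior against posterior and 90% in left against field, and 100% of 6-fold changes in each. Unchanged genes called higher and lower were then 4 and 14 in the node comparison, 79 and 67 in atrium against ventricle, 1 and 6 in the junction, and 0 and 5 in the pacemaker field. The comparison of heart with mesoderm was not simulated.

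Alternatives fixed in advance were DESeq2 1.42.0 size factors, total counts alone, the authors' normalized CPM, a 4-fold limit, a floor of 1 CPM, a pseudocount of 0.1 CPM, the mean of the references in place of each, and leaving out each reference library. Chosen after seeing the data were scaling without mitochondrial genes, scaling without erythroid genes, and thinning all libraries at random to 10258697 counts, the total of the shallowest. Mitochondrial genes held 10.5% to 19.4% of counts and the 10 most abundant genes 10.9% to 19.3%. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Strand, duplicate reads and splice forms were left out, since gene counts do not hold them.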

Results

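RNA was sequenced from 8 pools of dissected chick embryo tissue, with 1 library per pool. The heart gave 4 libraries: the developing sinoatrial node, which is the pacemaker region at the venous inflow, the left atrium, the apex of the ventricle, and the atrioventricular junction between the chambers. The other 4 libraries came from the lateral plate mesoderm, the sheet whose front part forms the heart, at Hamburger-Hamilton (HH) stage 8: the progenitor field of the pacemaker, and the anterior, left and posterior parts of the plate. The junction was taken at HH 17 to 18, and the stages of the other 3 heart libraries were not given in the sources used here. Counts assigned to genes summed to 10258697 in the ventricle, 10757964 in the posterior mesoderm, 10837246 in the anterior mesoderm, 13518277 in the junction, 14047021 in the node, 14584736 in the left mesoderm, 16110771 in the pacemaker field and 17189803 in the atrium. Between 14228 and 14961 of the 17778 listed genes had at least 1 count per library. Levels are given as CPM, counts scaled to a common library size, after scaling between libraries. With 1 library per group no difference has a replicate check and no p-value is given. A gene was called higher or lower when it differed by at least 2-fold from every reference library, reached 5 CPM in the higher library, and had a 95% counting interval that excluded no difference. Folds are given to the nearest reference with that interval in brackets, and the intervals cover counting error only. PCR copies of 1 molecule are not independent, so the true intervals are wider.

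The 8 libraries fell into the earlier mesoderm and the later heart. Among the 6 pairs of mesoderm libraries, Spearman correlations across 12984 genes ran from 0.986 to 0.991, and between 49 and 176 genes were called different in a pair. Heart pairs had correlations of 0.945 to 0.970 with 650 to 1130 called genes. The 16 pairs that crossed from heart to mesoderm had 0.837 to 0.868 and 2123 to 2871. The closest pair was the left mesoderm and the pacemaker field, with 0.991 and 49 genes. These correlations are across genes, which are not independent replicates, and the number of genes called in the closest pairs is the only yardstick here for how far libraries of similar tissue differ.

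The first question, as the series states it, was how the inflow region with the pacemaker differs from the atrium and ventricle. The node library carried pacemaker genes at higher levels than both chambers: ISL1 and TBX3, transcription factors of the sinoatrial node, HCN4, the channel of the pacemaker current, and CACNA1G, a T-type calcium channel. NKX2-5, a heart transcription factor that restrains the pacemaker programme, and GJA5, a connexin of fast-conducting gap junctions, were lower there. Most measured HOX genes (3 of 4) and genes of the epicardium, the outer cell layer of the heart (4 of 6), were higher in the node as well. In all, 304 genes were called higher and 143 lower than both chambers among 9787 expressed genes. Of these, 181 and 89 carried a gene symbol. The stages of the node, atrium and ventricle libraries were not given, so region and stage may differ together here. The atrium was sampled on the left only, so region and side may differ together as well.

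Of 11 measured members of the pacemaker list, 6 were called higher and none lower, and the list's median log2 ratio of 1.64 lay at percentile 100 of 10000 random lists matched on expression. ISL1 stood at 17.6 CPM in the node against 0.343 in the atrium and 0.434 in the ventricle, a 40.5-fold difference (15.6 to 150). CACNA1G was 6.55-fold (4.85 to 9.02) and TBX3 2.78-fold (2.49 to 3.11) above the atrium. HCN4 reached 99.9 CPM in the node, 40.3 in the atrium and 21.5 in the ventricle, 2.48-fold (2.25 to 2.74) over the nearer chamber. BMP2 and BMP4, secreted growth factors, were 4.06-fold and 3.19-fold higher. The full BMP list had 2 of 6 members higher, with a median of 1.14. TBX2 was at 7.26 CPM in the node, 18.1 in the atrium and 1.63 in the ventricle and was not called.

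The ventricular list went the other way and the atrial list did not. In the ventricular list 3 of 7 measured members were lower and none higher (median log2 ratio -1.59, percentile 0), and in the atrial list none of 5 was called in either direction (median 0.28, percentile 97.5). The 3 lower members, MPPED2, KCNJ2 and GJA5, were not called between atrium and ventricle. HEY2 and FHL2, which were higher in the ventricle than in the atrium, were not called in the node. A lower call needs a node level 2-fold below both chambers, which genes already low in 1 chamber could hardly reach. The log2 ratio to the mean of the chambers was -1.61 for HEY2 and 0.81 for FHL2. The calls thus cannot show whether genes particular to 1 chamber were lost in the node. NKX2-5 was at 120.2 CPM in the node against 1123 in the atrium and 594 in the ventricle, 4.95-fold lower (4.68 to 5.23). GJA5 was at 61.4 CPM against 329 and 571, a 5.36-fold gap (4.99 to 5.77). PROX1 was 9.40-fold lower (6.48 to 14.1), MYOZ2, a Z-disc protein, 16.3-fold (11.5 to 23.9), and KCNJ2, the inward rectifier that holds the resting potential of working muscle, 4.62-fold. FN1, which encodes fibronectin, was at 423 CPM against 2460 and 3037. Few contractile genes were called: 1 of 19 sarcomere members was higher (ACTA2, smooth muscle actin, 2.55-fold), 1 was lower (LDB3, 2.37-fold), and the median was -0.22. Calcium handling genes had none of 7 called, with ATP2A2 at 3686, 2448 and 1433 CPM and RYR2 at 228, 142 and 101 in node, atrium and ventricle. NPPA, the atrial natriuretic peptide, stood at 599.5 CPM in the node, between 197 in the atrium and 1224 in the ventricle. NR2F2, an atrial identity factor, was at 382, 206 and 20.5 CPM in the same order and was not called, and neither was MYL2 at 5460, 8064 and 5432.

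Signalling and patterning genes formed another part of the higher set. HOX genes had 3 of 4 measured members higher (median 2.93). HOXA4 was at 14.9 CPM against 0.206 and 0.217, 68.9-fold (18.8 to 572.3) over a ventricle value of 2 counts. HOXA3 was 12.2-fold (7.81 to 20.1) and HOXB3 5.76-fold higher. In the retinoic acid list 3 of 8 members were higher and RARB was lower by 2.14-fold; ALDH1A2, which makes retinoic acid, was at 517 CPM against 252 and 169, and CYP26A1, which degrades it, was 5.03-fold higher. Active Wnt genes had 2 of 6 higher and 1 lower. RSPO3, which amplifies Wnt signals, was at 199.9 CPM in the node against 36.0 and 12.5, and WNT11 was 3.12-fold lower. Among secreted Wnt antagonists 3 of 6 were higher, with SFRP2 at 5.05-fold and SFRP1 at 2.81-fold, while DKK3 was 3.51-fold lower. In the extracellular matrix list 5 of 16 members were higher and none lower (median 0.63, percentile 100), such as COL6A3 at 4.46-fold, COL3A1 at 3.30-fold and ELN, elastin, at 3.10-fold. The cushion list, of genes of the atrioventricular canal and of the cushion mesenchyme that forms the valves, was mixed, with 6 of 15 higher and 3 lower.

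Named genes outside the lists that were higher in the node included SCARB1, a lipoprotein receptor (57.2 CPM against 2.81 and 2.93, 19.5-fold, 13.3 to 29.8), OIT3 (91.0 CPM, 16.8-fold), FLRT3, a membrane protein that binds fibroblast growth factor receptors and adhesion partners (118 CPM, 15.9-fold), FHDC1 and SLCO2A1 (both 19.2-fold), SGK1, a kinase (7.48-fold), and CHGB, a secretory granule protein (152 CPM, 7.21-fold). Markers of neighbouring cell types moved alongside. Epicardial markers had 4 of 6 members higher (median 1.27), with TCF21 at 138 CPM against 15.9 and 23.3. Early endoderm and liver markers had 3 of 4 higher (median 2.52): APOA1 was at 1489 CPM against 635 and 98.4, and FGA at 6.68 CPM against 0 counts in both chambers, at least 20.5-fold. Endothelial markers had 1 of 13 higher (VWF, 5.61-fold) and 1 lower (NFATC1, 2.62-fold), with a median of -0.05, and erythroid markers had none of 9 called, with a median of -0.33. The proliferation list had none of 12 called, with a median of -0.30. Scaling by total counts shifted the median gene by 0.18 log2 units and gave 414 higher and 95 lower genes in place of 304 and 143. Without the atrium library 681 were higher and 449 lower than the ventricle, and without the ventricle library 437 were higher and 285 lower than the atrium.

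**Figure D1:**
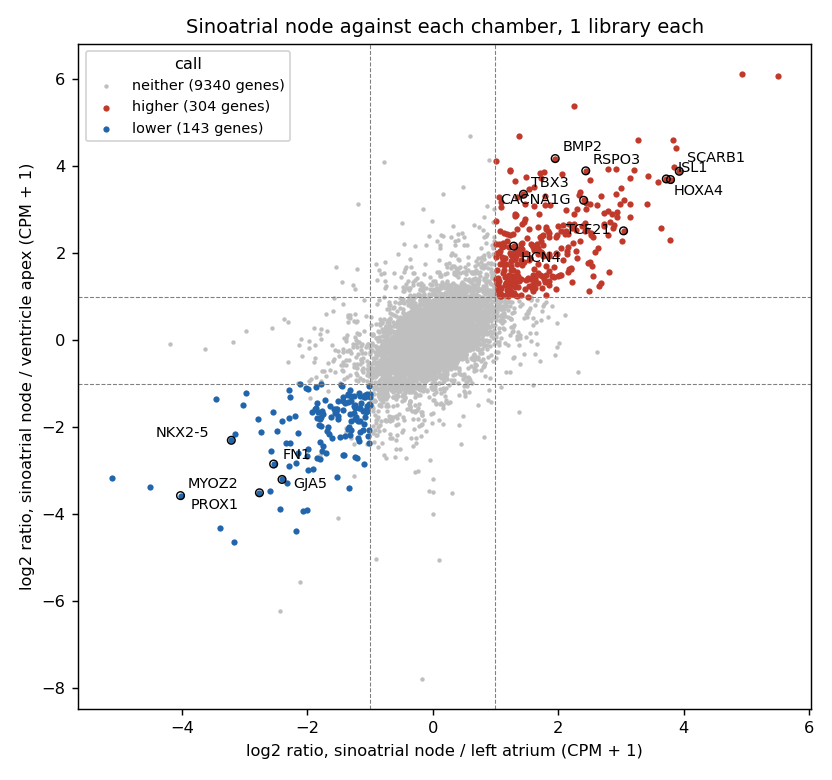
Each point is a gene, placed by its log2 ratio of the sinoatrial node library to the left atrium (horizontal) and to the ventricle apex (vertical), from CPM + 1, with dashed lines at the 2-fold limits; 304 genes called higher are red, 143 called lower are blue and the others grey. ISL1, TBX3 and HCN4 lie on the higher side of both axes, and NKX2-5 and GJA5 on the lower side.

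The working chambers were then compared with each other. The atrium carried NR2F2, TBX5 and GATA6, factors of atrial and inflow identity, at higher levels, and the ventricle carried HEY2, a ventricular repressor of atrial genes, and HMX1. NPPA was 6.2-fold higher in the ventricle. Blood markers were also higher in the atrium library. The rule called 406 genes higher in the atrium and 292 higher in the ventricle of 9441 expressed. This excess on the atrial side depends on the scaling, since total counts alone gave 301 and 307. Neither library has a stated stage, so chamber and stage may differ together. With the atrium sampled on the left only, chamber and side may do so too.

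In the atrial list 3 of 5 members were higher in the atrium and NPPA was lower (median 1.07). NR2F2 was at 206 CPM against 20.5, 10.03-fold (8.65 to 11.7), TBX5 at 777 against 308, 2.52-fold (2.42 to 2.62), and HEY1 at 32.5 against 15.0. The ventricular list had none of 7 higher and 2 lower (median -0.79). HEY2 was at 19.8 CPM in the atrium and 292 in the ventricle, 14.8-fold (13.1 to 16.7), and FHL2 was 4.93-fold higher in the ventricle. HMX1 had 14.9 CPM in the ventricle and 0 counts in the atrium, a gap of at least 72.2-fold. The pacemaker list had 5 of 9 members higher in the atrium and 1 lower (median 1.31), including TBX3 at 4.16-fold and CACNA1D at 4.05-fold. HCN4, at 40.3 and 21.5 CPM, was not called. Cardiac transcription factors had 3 of 11 higher and none lower (median 0.49), with GATA6 at 4.09-fold and GATA5 at 2.24-fold. NKX2-5, at 1123 and 594 CPM, and GJA5, at 329 and 571, stayed inside the limit of 2-fold. The sarcomere list had 2 of 19 higher and 1 lower with a median of 0.00. MYL2 was at 8064 and 5432 CPM.

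The cushion list, of atrioventricular canal and cushion mesenchyme genes, had 7 of 15 members higher in the atrium and none lower (median 0.60). The 8 members not called included VCAN, HAPLN1 and SNAI2, with log2 ratios of -0.01, 0.04 and 0.08. TBX2 was 11.1-fold (6.63 to 20.2), SOX9 5.59-fold and MSX2 4.19-fold higher, and BMP2 was 6.16-fold higher. Active Wnt genes had 3 of 6 higher and none lower, with WNT11 at 51.8 CPM against 17.0 and WNT9A at 20.9-fold (6.94 to 102.9) over 3 counts. ADM, the vasodilator adrenomedullin, was 15.5-fold and SOD3, an extracellular superoxide dismutase, 21.0-fold (9.47 to 57.8) higher. Erythroid markers had 6 of 9 members higher and none lower (median 1.04, percentile 100). HBBA, a beta globin, was at 14730 CPM in the atrium and 6452 in the ventricle, and KLF1, an erythroid transcription factor, was 2.64-fold higher. The globin genes are close copies of one another, so the split of reads among them is uncertain. Endothelial markers had 1 of 12 higher (ESAM, 2.11-fold) and 3 lower, with CD34 and ROBO4 each 2.25-fold and SOX7 2.16-fold higher in the ventricle. Extracellular matrix genes had 2 of 15 higher and none lower (median -0.26).

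The atrioventricular junction, which later forms valves and slows conduction between the chambers, was compared with the node, the atrium and the ventricle. Genes of the atrioventricular canal and the endocardial cushions, the tissue of the later valves, were among its higher genes. MSX2, SOX9, TBX2 and HAPLN1 lay above all 3 other regions. TEK and SOX7, endothelial genes, and NPPA were lower. The rule called 82 genes higher and 51 lower of 9916. Of 15 members of the cushion list, 5 were higher and none lower (median 1.88, percentile 100). MSX2 was at 83.8 CPM in the junction and 10.9 in the atrium, 7.68-fold (6.49 to 9.14). SOX9, at 65.1 CPM, was 4.17-fold over the node. HAPLN1, which links hyaluronan to proteoglycans, was 4.12-fold higher, and ACAN, the proteoglycan aggrecan, 6.89-fold. TBX2 was at 39.1 CPM against 7.26, 18.1 and 1.63 in node, atrium and ventricle. TBX3 at 95.1 CPM and BMP2 at 55.6 were near the node's levels and were not called. Extracellular matrix genes had 3 of 16 higher and none lower, with LAMA2 at 2.36-fold, LAMA4 at 2.28-fold and FBLN1 at 2.19-fold.

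Genes outside the lists that were higher in the junction included CBLN1 (6.95-fold), PENK, the enkephalin precursor (8.16-fold), PDE1C, a calcium-dependent phosphodiesterase (5.39-fold) and COLQ (4.37-fold). The pacemaker list had none of 11 members called, with a median of 0.60 at percentile 99.95, and HCN4 was at 69.9 CPM. Among active Wnt genes 1 of 7 was higher, WNT4 at 2.5-fold. Epicardial markers had 1 of 6 higher (median 1.17), the guidance cue SEMA3D at 2.94-fold. Endothelial markers had none of 13 higher and 2 lower (median -0.78, percentile 0), and erythroid markers had none of 9 called (median -0.67, percentile 0). TEK, an endothelial receptor, was at 7.56 CPM against 38.8, 29.3 and 55.0, 3.88-fold below the atrium. NPPA was at 72.8 CPM, 2.71-fold below the atrium. SERPINE2 was 3.03-fold and RDH10, a retinol dehydrogenase, 3.16-fold lower. The sarcomere list had none of 19 called. As this region is the only one with a stated stage, region and stage may differ together. Without the node library 205 genes were higher and 150 lower, without the atrium 143 and 89, and without the ventricle 129 and 87.

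**Figure D2:**
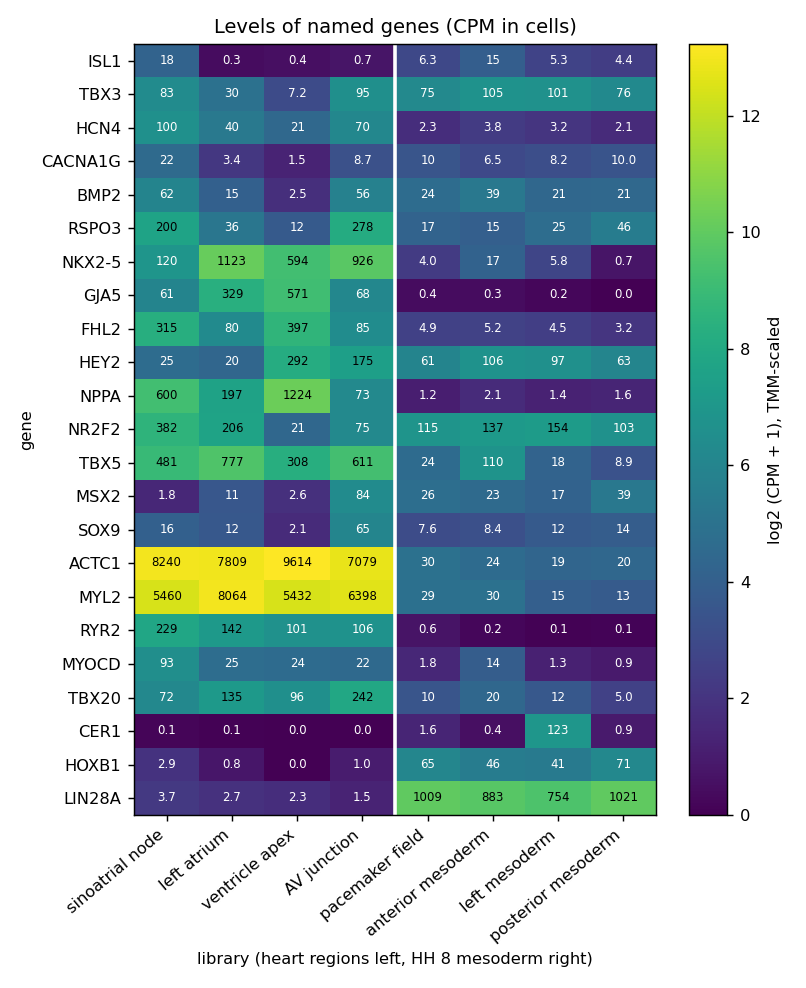
Heat map of named genes (vertical) in the 8 libraries (horizontal, heart regions left of the white line and HH 8 mesoderm right), coloured by log2 of CPM + 1 with the CPM printed in each cell. ISL1 is highest in the sinoatrial node at 17.6 CPM, HEY2 in the ventricle at 292 CPM, MSX2 in the junction at 83.8 CPM and CER1 in the left mesoderm at 123 CPM.

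At HH 8, the pacemaker progenitor field was set beside the other 3 mesoderm libraries. Its profile was close to theirs: 5 genes were called higher, none lower, of 9264 expressed. SCUBE3, a secreted and membrane-tethered protein of the EGF-repeat family, was by far the most different, at 295 CPM against 2.36 in the anterior, 3.41 in the left and 4.80 in the posterior mesoderm, 61.4-fold (47.2 to 81.4) over the nearest. LRRC52, a leucine-rich repeat protein, was at 19.4 CPM against 1.05, 0.868 and 0.515, 18.5-fold (10.4 to 36.1). SCARB1 was at 44.8 CPM against 5.24, 6.65 and 7.12, 6.30-fold (5.02 to 7.99). The remaining pair was outside the naming rule and is named after its values were seen: SLC2A5, a fructose transporter, at 9.25 CPM against 1.40, 1.45 and 1.03, and SNORA3, which carries the name of a small nucleolar RNA, at 13.1 CPM against 4.37, 0.405 and 0.944. In the coordinates of the files, whose genome build was not given in the sources used here, SCUBE3 lies on chromosome 26 from 3968671 to 3988834 (minus strand), LRRC52 on chromosome 8 from 5739587 to 5741680 (plus strand) and SCARB1 on chromosome 15 from 4543038 to 4559251 (plus strand). SNORA3 lies within RPL27A (3396 CPM in the field), LRRC52 overlaps MGST3 on the same strand (196 CPM) and SCARB1 overlaps UBB on the other strand (1573 CPM), so reads of these pairs may not be told apart. None of the 3 overlapping genes was called.

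No list member was called in the field. ISL1 was at 6.27 CPM in the field, 14.7 in the anterior, 5.32 in the left and 4.38 in the posterior mesoderm. NKX2-5 stood at 4.003, 16.9, 5.79 and 0.686 CPM in the same order, and TBX5 at 24.0, 110.4, 17.6 and 8.92. The field lay between anterior and posterior in these 3 heart genes. BMP2 was at 24.3 CPM against 38.9, 20.7 and 20.9, HAND2 at 204 against 284, 264 and 162, and WNT8A, listed in the files as WNT8C, at 4.49 against 3.67, 7.99 and 20.5. The list medians were small: -0.11 for cardiac transcription factors (12 members, percentile 2.3) and -0.15 for pacemaker genes (7, percentile 2.54). They were -0.23 for active Wnt genes (10, percentile 0.04), -0.23 for HOX genes (8, percentile 0.15) and 0.35 for erythroid markers (7, percentile 99.99). The list of left-right genes had a median of -0.23 over 7 members (percentile 0.06), and endoderm markers -0.21 over 7 (percentile 0.1). Leaving out the posterior library gave 4 lower genes, the anterior library 1 and the left library none, and the count of higher genes lay between 5 and 7.

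**Figure D3:**
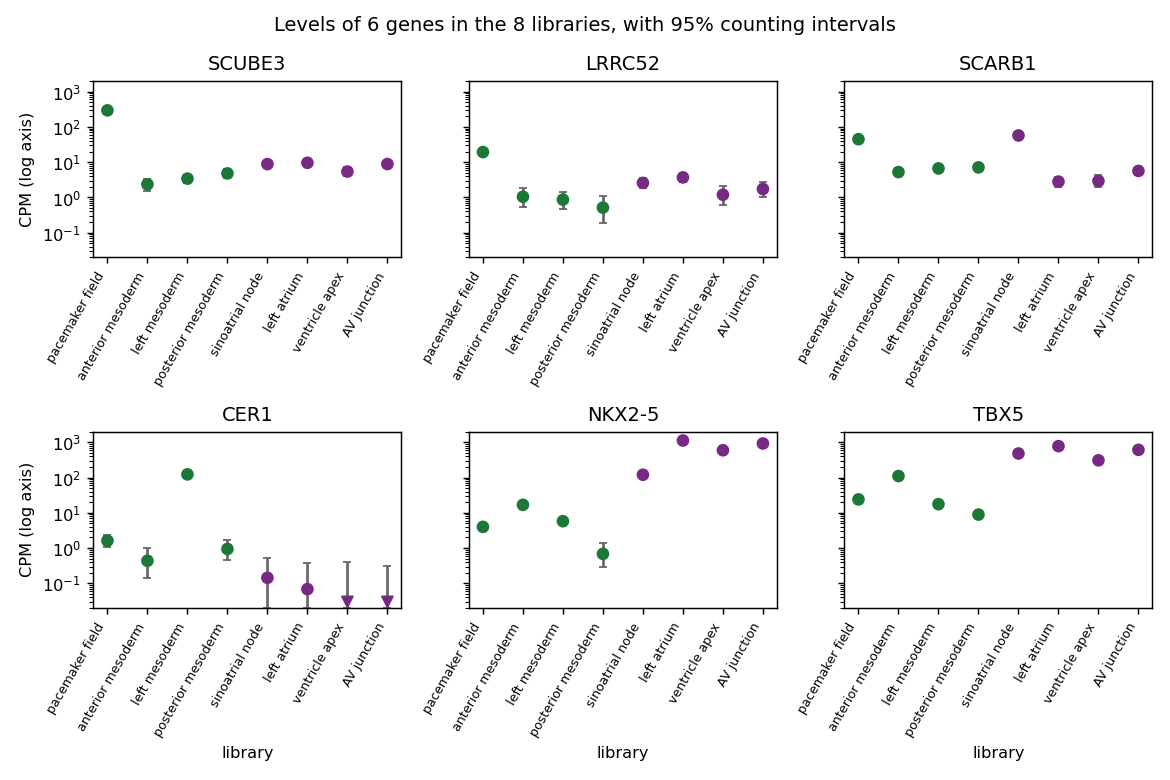
Level of SCUBE3, LRRC52, SCARB1, CER1, NKX2-5 and TBX5 in each of the 8 libraries (horizontal; green for mesoderm, purple for heart), as CPM on a log axis, with bars for the 95% counting interval and triangles for 0 counts. SCUBE3 reaches 295 CPM in the pacemaker field and 9.61 CPM at most in the other 7 libraries, and SCARB1 is high in both the field (44.8 CPM) and the sinoatrial node (57.2 CPM).

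Whether the field's genes are also the node's was counted directly. Among 8664 genes expressed in both comparisons, which hold 3 of the field's 5 genes and 193 genes called higher in the node, 1 gene, SCARB1, was called higher in both, where independent lists would share 0.07. Those comparisons have no library in common.

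Along the axis of the lateral plate, the anterior mesoderm carried higher levels of early heart factors. TBX5, NKX2-5, MYOCD and MEF2C, transcription factors and a cofactor of heart muscle, were higher anteriorly, and WNT8A, CDX4 and HOXB5 were higher posteriorly. The rule called 82 genes higher and 94 lower in the anterior library of 9056 expressed. Cardiac transcription factors had 7 of 12 members higher and none lower (median 1.38, percentile 100). NKX2-5 was at 16.9 CPM against 0.686, 24.6-fold (12.2 to 57.7), TBX5 at 110.4 against 8.92, 12.4-fold (10.1 to 15.3), MYOCD 14.5-fold (7.91 to 29.7) and MEF2C 6.62-fold. TBX20 was 4.06-fold, ISL1 3.36-fold and GATA4 2.35-fold higher. Contractile genes had 4 of 9 sarcomere members higher and none lower (median 0.39), with TNNT2, cardiac troponin T, at 694 CPM against 297, ACTA2 at 2.96-fold and TNNI1 at 2.14-fold. In the ventricular list 2 of 5 were higher, MYL2 at 2.30-fold and LBH at 2.23-fold. HAS2, which makes hyaluronan, was 3.31-fold and GATA3 5.96-fold higher.

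On the posterior side, active Wnt genes had 2 of 10 members lower in the anterior library and 1 higher (median -0.59). WNT8A was at 20.5 CPM posteriorly and 3.67 anteriorly, 5.59-fold (4.01 to 7.95), RSPO3 was 3.13-fold higher posteriorly, and WNT2B was 3.40-fold higher anteriorly. HOX genes had none of 8 higher and 3 lower (median -0.70): HOXB5 was 3.88-fold, HOXB8 3.08-fold and HOXB3 2.58-fold higher in the posterior library. CDX4, a caudal factor that regulates HOX genes, was at 19.3 CPM against 4.28. Paraxial and streak genes had 1 of 5 higher and 2 lower, with TBX6 at 2.80-fold. LHX1, a factor of intermediate mesoderm, was 6.03-fold and PITX1, a hindlimb field factor, 5.14-fold higher posteriorly. Endoderm markers had none of 7 higher and 2 lower, TTR at 2.25-fold and APOH at 3.15-fold, and epicardial markers had none of 7 higher and 2 lower, with a median of 0.34 (percentile 99.7). Erythroid markers had none of 7 called (median -0.01). In counts simulated for this comparison, 20% variation between libraries was assumed. With it 86 unchanged genes were called higher and 87 lower, and 100% of 6-fold increases were recovered. The same setting gave 68 and 66 such calls for the left mesoderm against the pacemaker field, where the real pair had 39 and 10. The assumed variation may thus be too large for the mesoderm, and the 86 and 87 do not measure how many real calls are noise.

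The left mesoderm was compared with the pacemaker field, whose side the labels do not state. CER1, a secreted antagonist of the left-side programme, had the largest fold among the named genes higher on the left. It was at 123 CPM against 1.62, 75.9-fold (53.0 to 112.7). CER1 lies on chromosome Z from 31404226 to 31405322 in the files' coordinates. The rule called 39 genes higher and 10 lower of 9046. Left-right genes had 2 of 7 members higher and none lower, with a median of -0.02. ELN was 11.5-fold (8.40 to 16.2), CD3E 10.8-fold, WNT2B 5.03-fold and TNC, the matrix protein tenascin C, 2.27-fold higher on the left. SCUBE3, LRRC52 and SCARB1 were 86.4-fold, 22.3-fold and 6.74-fold lower in the left library, as the field comparison, which includes this pair, already required. Extracellular matrix genes had 2 of 12 higher and none lower. Erythroid markers had none of 7 called, with a median of -0.39 at percentile 0.01, and epicardial markers none of 6, with a median of -0.36. In counts simulated for this comparison with the same assumed variation, 68 unchanged genes were called higher and 66 lower, more than the real pair gave.

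**Figure D4:**
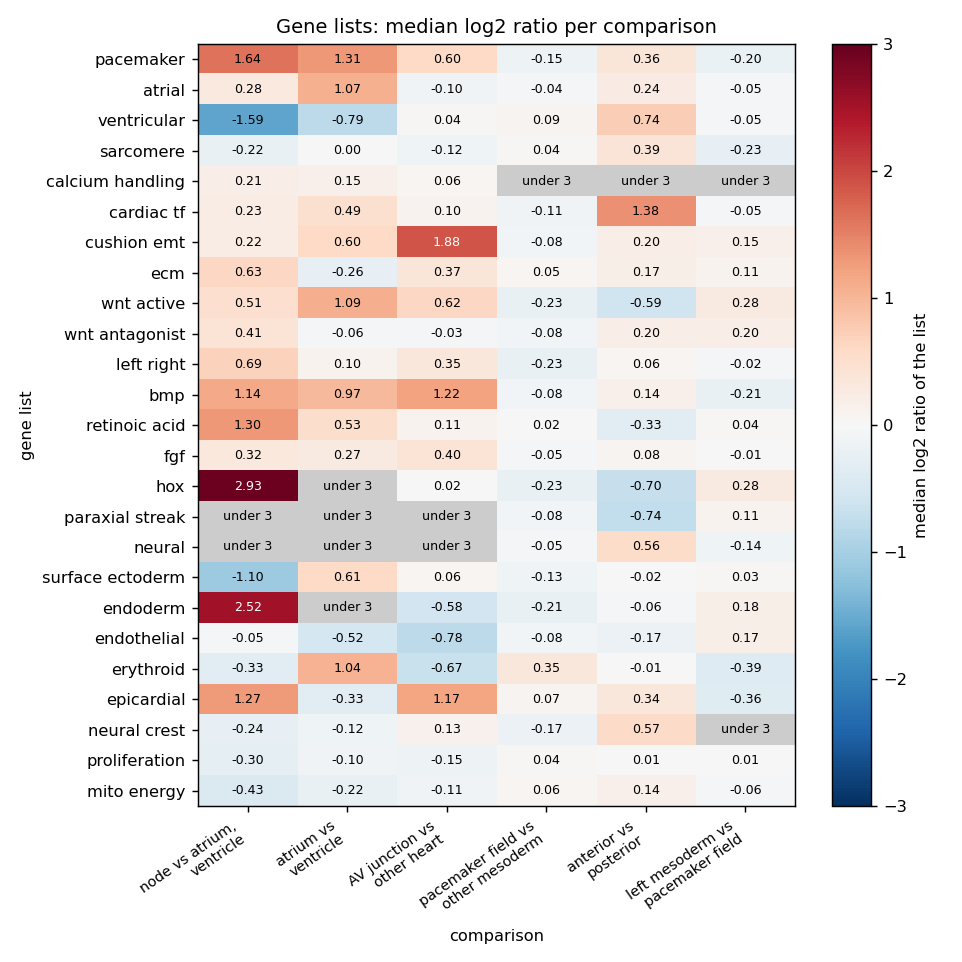
Heat map of the median log2 ratio of each of 25 gene lists (vertical) in the 6 comparisons within the heart or within the mesoderm (horizontal), with the value in each cell and grey where under 3 members were measured. The pacemaker list reaches 1.64 in the node and the cushion list 1.88 in the junction, while in the pacemaker field no list median lies outside -0.23 to 0.35.

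The 4 heart libraries together were set against the 4 mesoderm libraries, so that a gene counted only where its lowest level on one side exceeded its highest on the other. Most measured genes of heart muscle (18 of 19 sarcomere members) and blood (6 of 9) were higher in every heart region, and most endoderm genes (5 of 8) were lower. The rule called 587 genes higher and 265 lower of 10454. Sarcomere genes had 18 of 19 members higher and none lower (median 6.24). ACTC1, cardiac actin, ran from 7079 to 9614 CPM in the heart and from 18.6 to 29.6 in the mesoderm, 238.8-fold at the nearest pair. MYBPC3 was 357.6-fold, ACTN2 240.9-fold, CSRP3 197.5-fold and MYL2 180.2-fold higher. Calcium handling genes had 6 of 7 higher (median 4.66), with RYR2, the calcium release channel, at 169.2-fold (94.2 to 340.2), CASQ2 at 83.4-fold and CACNA1C at 45.2-fold. Ventricular genes had 4 of 7 higher (median 4.49). Cardiac transcription factors had 4 of 12 higher and none lower (median 1.69), such as NKX2-5 at 7.13-fold and TBX20 at 3.57-fold. In the pacemaker list 2 of 12 were higher and 1 lower, with HCN4 at 5.59-fold. Outside the lists, TECRL was 451.1-fold (297.7 to 720.3) and SYNPO2L 437-fold higher.

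Among genes lower in all heart regions, LIN28A, an RNA-binding protein of early embryonic cells, was at 754 to 1021 CPM in the mesoderm and 1.48 to 3.66 in the heart, 205.9-fold at the nearest pair (156.5 to 276.6). FST, the activin antagonist follistatin, was 167.5-fold (65.1 to 616.5) and SHH 92.9-fold lower. Endoderm markers had none of 8 higher and 5 lower (median -4.59), retinoic acid genes 1 of 10 higher and 5 lower (median -2.10), and HOX genes none of 9 higher and 3 lower. CRABP1 was 12.8-fold and HOXB1 14.4-fold lower. Fibroblast growth factor genes had none of 7 higher and 2 lower, with FGFR2 at 3.41-fold, and surface ectoderm markers none of 6 higher and 2 lower. Erythroid markers had 6 of 9 higher, led by HBBA at 327.5-fold, and endothelial markers 4 of 13 higher and 1 lower (median 1.56). The proliferation list had none of 12 called (median -0.46). Scaling by total counts shifted the median gene by -0.30 log2 units and gave 433 higher and 472 lower genes in place of 587 and 265. The mesoderm was at HH 8 and the junction at HH 17 to 18, so tissue and stage differ together in this contrast. The stages of the other 3 heart libraries were not given.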

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

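Scaling without mitochondrial genes, scaling without erythroid genes and thinning to equal depth were chosen after the data were seen. None of the 14 counts of called genes moved by more than 1.5 times under these, and none of 15 counts, the overlap included, did so under DESeq2 size factors. No gene called in a comparison was called in the opposite direction under any alternative, but this outcome was all but fixed. The DESeq2 and total-count scalings shifted the median gene by at most 0.30 log2 units, and a reversal needs a ratio to pass from 1 to -1. The other alternatives change limits, references, the pseudocount, counting noise or, slightly, the scaling. Between field and node 1 gene was shared under each of the 6 settings tried. With total counts alone, or the authors' normalized CPM, which are the same scaling, genes lower in the node fell in number to 95 and genes lower in the heart rose to 472, and 59 of the 163 list medians and 125 named gene ratios moved beyond their counting spread, against 1 and 7 under DESeq2.

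A stricter limit leaves fewer genes by construction. At 4-fold, 77 genes were higher and 26 lower in the node, 73 and 38 in the atrium against the ventricle, 12 and 5 in the junction, 9 and 9 in the anterior mesoderm, 8 and 5 in the left mesoderm, and 270 and 96 in the heart against the mesoderm. A floor of 1 CPM admits more genes and gave 8 higher in the pacemaker field, 165 lower in the anterior and 22 lower in the left mesoderm, and a pseudocount of 0.1 CPM gave 18 lower in the left. Against the mean of the references 320 genes were lower in the node, 216 higher and 282 lower in the junction, and 17 lower in the pacemaker field. Dropping a reference can only add calls. Leaving out each reference in turn, or in the heart comparison each library, gave 437 to 681 higher and 285 to 449 lower genes in the node, 129 to 205 and 87 to 150 in the junction, 5 to 7 and 0 to 4 in the pacemaker field, and 604 to 692 and 277 to 330 in the heart. Over all genes with a count, the closest pair of libraries correlated at 0.989, and 27 of the 28 pairs moved beyond their counting spread. No paired analysis was possible because each group is 1 library and the result comes from no test. Depth limits genes near 1 read, worth 0.0582 to 0.0975 CPM, and variation between libraries of 1 tissue could not be measured.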

Other observations

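The comparison of node and junction together with both chambers was chosen after the data were seen, as were the tests below of a smaller muscle share, of adjoining tissue, of blood cells and of RNA from another library. The node and the junction, the slowly conducting parts of the heart, shared a set of genes against both working chambers: 86 genes were higher in both and 43 lower in both, of 9916 expressed. Among those higher were TBX3, CACNA1G and BMP4 (3 of 11 pacemaker genes), 3 of 6 epicardial genes, and 6 of 15 members of the cushion list. The cushion list also had 1 lower member, and TBX3 is counted in it as well as in the pacemaker list. RSPO3 was at 199.9 CPM in the node and 278.1 in the junction against 36.0 in the atrium and 12.5 in the ventricle, TCF21 at 138 and 140.0 against 15.9 and 23.3, BMP2 at 62.4 and 55.6 against 15.4 and 2.496, and SNAI2, a factor of cells that leave an epithelium, at 28.9 and 40.9 against 8.30 and 7.81. SULF2, an enzyme that trims heparan sulphate, was at 82.4 and 134 CPM against 18.7 and 22.0, and COL3A1 at 81.3 and 82.3 against 20.4 and 24.6. Lower in both were GJA5, at 61.4 and 68.3 CPM against 329 and 571, FHL1, a muscle protein, at 20.8 and 13.3 against 105.1 and 159, and FN1, at 423 and 943 against 2460 and 3037. None of 19 sarcomere genes and none of 7 calcium handling genes was called in this comparison. How many genes such a pair of regions shares without a common programme was not tested.

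Epicardial, endoderm and HOX genes were higher in the node library. A smaller share of muscle cells, made up by all other cell types alike, would raise the markers of each. The endothelial list had a median log2 ratio of -0.05 (quartiles -1.15 to 0.10) against 1.27 (0.99 to 1.65) for the epicardial list, which argues against that as the whole cause. A share made up by 1 cell type alone could leave endothelial genes unchanged, so this list cannot decide it. The sarcomere list had a median of -0.22 (quartiles -0.41 to 0.20). After thinning to equal depth 10 of 10 called members were still called. Thinning leaves the CPM ratios unchanged apart from counting noise, so this says little about a difference in depth. Cells of tissue next to the node, carried along in the dissection, and expression by the node region itself cannot be told apart, since the region was dissected into 1 pool only, and the endoderm list's median of 2.52 would follow from either. The biological difference between regions stays open and untested.

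Erythroid genes were higher in the atrium library than in the ventricle library. After thinning to equal depth 6 of 6 called members were still called. Thinning leaves the CPM ratios unchanged apart from counting noise, and genes as abundant as the globins could hardly lose their call. The result therefore says little about depth. More blood cells in the atrium library would raise genes found only in blood cells by about 1 factor. Over all 9 measured members the largest fold was 2.28 times the smallest. The globins were 1.97-fold to 2.28-fold higher (with reads split among close copies), KLF1 had a log2 ratio of 1.28 and EPB42 of 1.04. HBAD, a globin (0.98), TAL1 (0.51) and TFRC (0.21) were not called. TAL1 is also in the endothelial list, whose median was -0.52 here, so the spread over members cannot decide against more blood cells. More blood cells and a difference in expression cannot be told apart. Globins held 4.7% of scaled counts in the atrium, 2.5% in the node, 2.23% in the ventricle and 1.76% in the junction.

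In the pacemaker field, SCUBE3 with 295 CPM and the other 4 higher genes stood out from a profile otherwise close to the other mesoderm. RNA of another library of the series is argued against for SCUBE3, LRRC52, SLC2A5 and SNORA3, since these 4 were above each of the 7 other libraries with counting intervals apart. SCARB1 was higher in the node, but its level in the field would need 75.3% of node RNA, which would bring 6208 CPM of ACTC1 where 29.6 was found. The 29 neighbouring genes were not raised as a set (median log2 ratio -0.01, largest 0.31), which argues against reads of neighbours that rose as well. For LRRC52, SCARB1 and SNORA3 these ratios cannot decide. A small share of reads from their more abundant overlapping genes would hardly change the ratios of those genes. Cells of a type outside the lists stay open, reads of the genes that overlap LRRC52, SCARB1 and SNORA3 were not separated, duplicate reads could not be examined in gene counts, and expression in the field itself may explain the pattern but stays a hypothesis with 1 library.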
